A study of Drosophila melanogaster with 24 samples.

How the data were processed

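Polyadenylated RNA was sequenced with strand information from 24 libraries of Drosophila melanogaster. Each library came from a pool of whole males, whole females, ovaries or testes that carried 1 of 2 transgenes under a ubiquitous tubulin-GAL4 driver and a temperature-sensitive GAL80 repressor. The control transgene expressed Dam, the bacterial DNA adenine methyltransferase, and the other expressed Dam joined to Polr2A (RpII215), the largest subunit of RNA polymerase II, here called Dam Pol II. The labels gave 3 replicates for each of the 8 combinations of tissue and transgene. Flies were kept at 18 °C and moved to 29 °C for 24 h before collection, and replicates were collected on different days, per the labels' protocols. Testis samples could include the seminal vesicle and ovaries kept the lateral oviduct, per the same protocols. Synthetic ERCC RNAs were added to every sample, from pool 78A in most and from pool 78B in whole male Dam replicate 1, whole male Dam Pol II replicate 3, whole female Dam Pol II replicates 2 and 3, ovary Dam replicate 1 and testis Dam Pol II replicate 3.

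The deposited values used here were raw read counts. The authors counted reads per gene with featureCounts 1.6.1 on the reverse strand, per the file headers, and the tables listed 17473 genes and 96 ERCC sequences. A separate deposited table held counts without regard to strand over 10918 intergenic regions, with a median length of 1059 bp. Reads had been handled with CASAVA 1.8.2, bcl2fastq 1.8, HISAT2 2.1.0, SAMtools 1.7 and deepTools 3.0.2, per the submitters' processing notes. The featureCounts command in the headers set no option for reads with several alignments or for reads over more than 1 gene, so that such reads were left out by the program's default. Counts of near-identical paralogs, such as Amy-p and Amy-d, Vm26Aa and Vm26Ab or the Mst84D genes, and of overlapping genes are therefore uncertain. The name of the genome build was not given in the sources used here. Of 17331 genes matched by identifier to a release 6 annotation, 98.8% had the same start and end, and gene positions are printed as the deposited tables give them. Symbols came from that annotation, and 142 genes without a match keep their identifier. The gene FBgn0010549 has a symbol there and is also printed by its identifier.

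Library sizes were the sums of gene counts without the ERCC sequences and ran from 3261841 to 11334122. At these sizes 3 counts, taken as the floor of detection in a library, stood for 0.265 to 0.920 counts-per-million (CPM). Where every library of a group was at 0, a fold change was given as a lower bound against 3 counts over the whole group. Floors and binomial intervals cover counting error only, since reads are not independent molecules. The p-values measure the spread between pooled samples.

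Each tissue was fitted apart, with 3 Dam Pol II libraries against 3 Dam libraries. Genes passed the expression filter of edgeR 4.0.16 by group, libraries were scaled by the trimmed mean of M-values (TMM), and genes were tested with the two-sided quasi-likelihood F-test of edgeR under R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and all adjusted p-values of genes and regions come from this test unless another is named. Standard errors (SE) of log2 fold changes were derived from the coefficient and its F statistic. The differences of the Dam Pol II effect between testis and ovary, between whole males and whole females, and among the 4 tissues were tested as interaction terms in 1 fit of all 24 libraries. Females were compared with males, and ovaries with testes, in the Dam libraries. Intergenic regions were tested in the same way with the library sizes and scaling factors of the gene counts. The share of counts in intergenic regions and the ERCC share were compared by two-sided exact permutation tests. Overlaps of calls between tissues were tested by one-sided Fisher's exact tests with Benjamini-Hochberg adjustment; no library was shared between tissues.

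Gene lists were tested as sets with camera of limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside the camera result, members called up, called down and not called were counted over all genes tested and adjusted over the list alone. Camera was also run with a correlation estimated from the residuals of each list, and none of the list calls under Dam Pol II passed then in any of the 4 tissues.

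The designs, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took Polr2A in every tissue, up to 10 called genes with the largest rise and up to 10 with the largest fall among those with a mean of at least 5 CPM and no overlap between transgenes, and up to 3 called members of each list by smallest p. It also took the 2 members with the smallest p of a list called by camera without a called member, and the 5 genes with the smallest p where fewer than 5 were called. In the sex comparisons it took the 5 highest, the 5 lowest and 3 per list, and in each interaction test the 5 genes with the smallest p. In each tissue it took up to 3 intergenic regions with the largest rise and fall, under the same 5 CPM and overlap conditions. Several regions named below lay under that mean. Members of a list could be named in describing that list. Genes chosen outside this rule are marked as chosen after their values were seen.

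The steps were tested on simulated counts with 200 changed genes drawn from the means and sizes of these libraries. The quasi-likelihood test recovered 1.52% of genes changed by 2-fold in whole males, 25.4% in whole females, 92.5% in ovary and 74.2% in testis, and 53.0%, 78.8%, 100% and 95.4% of those changed by 4-fold. In the sex comparisons it recovered 16.4% of 2-fold changes between whole animals and 81.5% between gonads. Most genes differed in the real sex comparisons, while the simulation changed 200 in either direction. Its rates there do not cover a shift in composition. False calls of this test numbered 4 of 40 in whole males, 15 of 88 in whole females, 10 of 190 in ovary and 10 of 139 in testis. Between whole animals they numbered 5 of 60 and between gonads 15 of 157. Each of these shares lay above the threshold for adjusted p-values, most so in whole females. The interaction step recovered 24.2% of 2-fold differences for testis against ovary and 11.9% for whole males against whole females. The intergenic step, run on testis, recovered 33.9% of 2-fold and 95.5% of 4-fold changes. Its counts were drawn with a fixed spread, not with a spread estimated from the regions. Counts of each pair of replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.64 to 74.3 over 24 pairs, and all 24 libraries were kept as separate replicates.

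Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors within edgeR, no expression filter, a filter of 5 CPM in 3 libraries, a minimum absolute log2 fold change of 1, a replicate block, 1 fit of all libraries, libraries with ERCC pool 78A only with and without scaling to the ERCC counts, and each library left out in turn. Fits that left out mitochondrial genes, or libraries with transcripts near 0 in other replicates of their group, were chosen after the data had been seen. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Signal tracks and raw reads were not analysed here.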

Results

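RNA from whole flies and gonads was sequenced to measure which transcripts changed when Dam Pol II was expressed in place of Dam. Dam fused to a chromatin protein methylates the DNA that protein contacts, and in targeted DamID the fusion with an RNA polymerase II subunit marks transcribed genes. Dam alone was the control named in the series design. In each tissue the Dam and the Dam Pol II libraries filled separate runs of adjacent columns in a plate row. The transgenes were also carried by different flies, whose genetic background was not compared. Plate position and any difference in background therefore went with the transgene and cannot be told from it. Changes with Dam Pol II below are differences between these groups of libraries. The 24 libraries fell into 8 groups of 3, from whole males, whole females, ovaries and testes with either transgene. Libraries held 3261841 to 11334122 gene counts in whole males and 4826842 to 9703273 in whole females. They held 6048306 to 8300740 in ovary and 6758442 to 10756190 in testis. The large mitochondrial rRNA took 5.31 to 20.5% of gene counts in whole males, 14.3 to 36.1% in whole females, 2.88 to 4.74% in ovary and 0.331 to 0.764% in testis. In whole females its share was 14.3 to 26.6% with Dam and 27.6 to 36.1% with Dam Pol II.

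Polr2A (FBgn0003277, X chromosome, 11562800 to 11570326, minus strand) encodes the subunit carried by the Dam Pol II transgene, and reads from the transgene's coding sequence can count toward it. In whole males it measured 38.5 ± 7.09 CPM (SD, n = 3) with Dam and 1060 ± 55.3 CPM with Dam Pol II, a log2 fold change of 4.78 (SE 0.25, adjusted p = 0.00234). In whole females it rose from 86.1 ± 5.24 to 372 ± 121 CPM, by 2.11 (SE 0.24, adjusted p = 0.0442). In testis it rose from 16.5 ± 4.83 to 79.98 ± 30.9 CPM, by 2.26 (SE 0.28, adjusted p = 0.00677). In ovary the Dam Pol II libraries, at 475 ± 228 CPM, all lay above the Dam libraries at 214 ± 7 CPM, but the log2 fold change of 1.15 (SE 0.25) did not pass the test (adjusted p = 0.0666). The rise was larger in whole males than in whole females by 2.76 on the log2 scale (SE 0.42, adjusted p = 0.00536 for the interaction). Of the 11 measured RNA polymerase II subunit genes, Polr2A alone was called in whole males, whole females and testis; the other 10 were not called in those tissues. In ovary none of the 11 was called by edgeR (2 at an unadjusted p under 0.05 and none by DESeq2), and 1, Polr2A, passed adjusted over the list alone. Camera called this list, Polr2A included, higher in whole males (mean 0.41, median 0.00033, 6 of 11 positive; adjusted p = 0.00384; adjusted p = 0.653 with an estimated correlation) and whole females (mean 0.33, median 0.21, 8 of 11 positive; adjusted p = 0.00715; adjusted p = 0.858 with an estimated correlation).

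**Figure D1:**
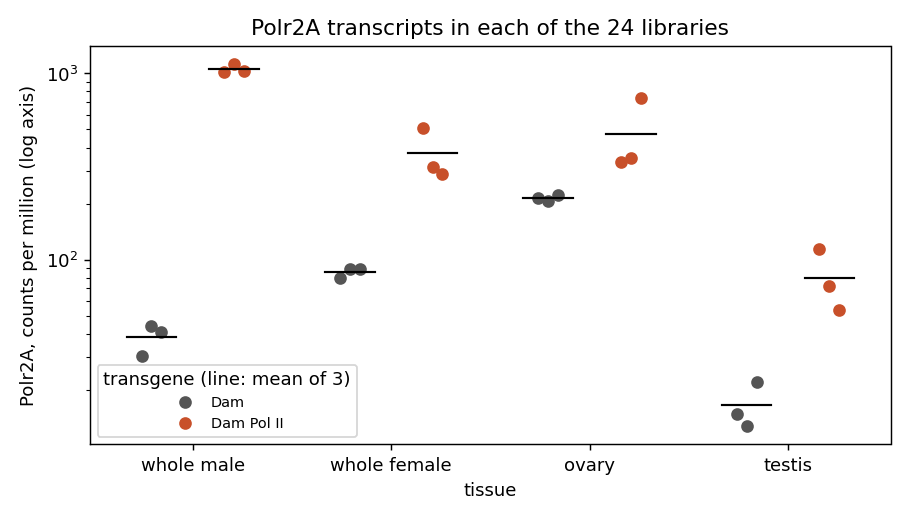
Polr2A in CPM (log axis) in each of the 24 libraries, by tissue and transgene; each point is a library and each line the mean of 3. Every Dam Pol II library lies above every Dam library of its tissue, and the means run from 16.5 CPM in testis with Dam to 1060 CPM in whole males with Dam Pol II.

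The ERCC share of counts, a measure of spike-in against fly RNA, was compared among libraries with pool 78A. It was 0.0990 ± 0.0166% with Dam and 0.0531 ± 0.00743% with Dam Pol II in whole males (n = 2 each, exact permutation p = 0.333, the smallest possible). Over both pools the direction in whole males turned, with 0.0993 ± 0.0118% and 0.139 ± 0.149% (n = 3 each, exact permutation p = 1), and in whole females, where 1 Dam Pol II library had pool 78A, the shares were 0.0447 ± 0.0133% and 0.0689 ± 0.0321% (n = 3 each, exact permutation p = 0.3). In ovary it was 0.00525 ± 0.000178% (n = 2) and 0.00372 ± 0.000289% (n = 3; exact permutation p = 0.1, the smallest possible). In testis it was 0.0321 ± 0.00559% (n = 3) and 0.0181 ± 0.000718% (n = 2; exact permutation p = 0.2, smallest possible 0.1). Scaling these libraries to their ERCC counts moved the median log2 fold change of all genes to 0.94 in whole males, 0.52 in ovary and 0.79 in testis, with 4512 genes called higher and 9 lower, 6052 and 21, and 6506 and 91. In whole females, with 3 Dam libraries and 1 Dam Pol II library, the median was -0.01. Polr2A exceeded the median of all genes by 4.73 in whole males, 2.57 in whole females, 1.16 in ovary and 2.44 in testis under this scaling. Changes below are relative to the other genes of the same library, as TMM scaling gives them.

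Whole males with Dam Pol II differed from those with Dam in Polr2A, while no other single gene passed the test in the fit of all whole male libraries. The pool 78A libraries alone, 2 per transgene, gave 1144 genes higher and 66 lower under TMM scaling. Leaving out only Dam replicate 1 or only Dam Pol II replicate 3, the libraries of the other pool, gave 1 called gene each. In the fit of all whole male libraries medians of several gene groups lay off 0 by small amounts. All 28 measured spermatid differentiation genes, which act in sperm formation, had positive log2 fold changes with a median of 0.67. Among them ocn measured 318 ± 93.1 CPM with Dam and 589 ± 107 CPM with Dam Pol II, and djl 90.6 ± 23.1 and 159 ± 36.0 CPM. Camera called this list higher (adjusted p = 8.93e-13; adjusted p = 0.653 with an estimated correlation). None of its members passed singly in edgeR, over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05 and none by DESeq2. Markers of several other organs lay lower: 18 of 18 muscle genes (median -0.40), 16 of 19 gut genes (median -0.44), 12 of 12 neuronal genes (median -0.36) and 11 of 11 photoreceptor genes (median -0.41) had negative values. Camera called these 4 lists lower with adjusted p of 4.95e-05, 0.000217, 0.00268 and 0.00711, and with an estimated correlation the adjusted p was 0.653, 0.653, 0.727 and 0.744. Scaling to the ERCC counts raised all genes together, to a median of 0.94, and thereby the 4 medians (0.37, 0.89, 0.81 and 1.04), so that their signs under it say nothing about these lists. The median of photoreceptor genes was positive (0.05) with the pool 78A libraries under TMM scaling. Gonadal soma markers were negative in 7 of 8 (median -0.28), while accessory gland and ejaculatory duct or bulb markers were positive in 15 of 21 (median 0.12), and camera called neither list (adjusted p = 0.185 and 0.0938). None of the members of the 4 lists passed in edgeR or DESeq2, and 0, 2, 0 and 0 had an unadjusted p under 0.05. The troponin I gene wupA measured 1745 ± 265 and 1281 ± 210 CPM and the rhodopsin gene Rh4 257 ± 14.9 and 194 ± 35.3 CPM. Fat body markers leaned the other way, with 7 of 8 positive and a median of 0.40. Camera gave an adjusted p of 0.00384, and of 0.653 with an estimated correlation. With the pool 78A libraries under TMM scaling the fat body median was 0.0078. The larval serum protein gene Lsp2 measured 4.49 ± 2.24 and 24.3 ± 6.99 CPM and passed adjusted over the list alone.

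In whole males 1 gene was called higher and 0 lower of 11676 tested, with 791 at an unadjusted p under 0.05 and 20 calls by DESeq2. After Polr2A the smallest p-values belonged to the cytochrome P450 gene Cyp4p2 (log2 fold change -5.39, SE 0.55, adjusted p = 0.101), the cuticle protein gene Cpr72Ec (-1.54, SE 0.17, adjusted p = 0.122), lncRNA:CR44344 (4.37, SE 0.54, adjusted p = 0.171) and CG31832 (4.01, SE 0.56, adjusted p = 0.354), none of which passed. The arms did not overlap for 13.1% of genes, against 10% by chance. Camera called 4 lists higher and 8 lower. Besides those above, detoxification genes were higher (median 0.22; adjusted p = 0.0171; adjusted p = 0.765 with an estimated correlation), though the direction of this test reversed without Dam replicate 1. Lower were cytosolic ribosomal proteins (median -0.16), ribosome biogenesis (-0.29), complex I (-0.24) and sex determination genes (-0.21), whose medians were 0.58, 0.63, 0.65 and 0.70 when scaled to the ERCC counts. Their adjusted p was 0.0242, 0.000508, 0.00268 and 0.0419, and with an estimated correlation it was 0.822, 0.653, 0.744 and 0.653. For cytosolic ribosomal proteins the direction of the test reversed without Dam replicate 3. Without Dam replicate 2 or Dam replicate 3 edgeR called 0 genes, with 351 and 867 at an unadjusted p under 0.05, and with the simulated recovery of 1.52% most 2-fold changes were not detectable at this spread.

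In whole females 2 fat body markers were called higher with Dam Pol II. The larval serum protein gene Lsp2 rose from 1.72 ± 0.686 to 272 ± 152 CPM (log2 fold change 7.26, SE 0.60, adjusted p = 0.0259) and the lipid carrier gene apolpp from 379 ± 62.4 to 1485 ± 188 CPM (1.97, SE 0.18, adjusted p = 0.0329). Of the 9 measured the other 7 were not called, and 7 were higher adjusted over the list alone, with a median of 1.97. Camera called the list higher (adjusted p = 1.48e-18), with adjusted p = 0.0704 with an estimated correlation. Yolk protein genes, which the fat body and the follicle cells transcribe, had a median of 1.54 (camera adjusted p = 3.1e-05; adjusted p = 0.482 with an estimated correlation). None of the 3 passed over all genes tested in edgeR (3 at an unadjusted p under 0.05 and 2 by DESeq2) and 3 passed adjusted over the list alone, among them Yp3 at 2096 ± 1308 and 8602 ± 1668 CPM. All 19 vitelline membrane and chorion genes, which build the eggshell, were positive with a median of 0.84 (camera adjusted p = 5.91e-05; adjusted p = 0.858 with an estimated correlation). None passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2, with 1 at an unadjusted p under 0.05.

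Other genes called higher in whole females were Vago, an antiviral factor (2.28, SE 0.19, adjusted p = 0.0259), the mitochondrially encoded complex I gene mt:ND5 (1.93, SE 0.20, adjusted p = 0.0391), Cyp6g1, a cytochrome P450 linked to insecticide resistance (1.52, SE 0.15, adjusted p = 0.0391), and CG11594 (1.21, SE 0.13, adjusted p = 0.0427), and CG9568 fell (-2.37, SE 0.26, adjusted p = 0.0442). The large mitochondrial rRNA took 27.6 to 36.1% of gene counts in the same Dam Pol II libraries, against 14.3 to 26.6% with Dam. Immune-induced genes had a median of 0.55, with PGRP-SC2 at 6.22 ± 4.22 and 88.3 ± 60.5 CPM (adjusted p = 0.11). Turandot and JAK/STAT genes had a median of 0.59, with the stress-induced TotA at 1.39 ± 0.778 and 9.65 ± 1.77 CPM (adjusted p = 0.0782). Neither gene passed over all genes tested. Adjusted over the list alone 1 immune gene was higher, and 3 Turandot and JAK/STAT genes were higher and 1 lower. Camera called both lists higher (adjusted p = 0.00715 and 0.00695), with adjusted p = 0.858 and 0.482 with an estimated correlation. Gut markers were negative in 13 of 14, with a median of -2.25 and wide spread between libraries (camera adjusted p = 0.00115; adjusted p = 0.858 with an estimated correlation). None of them passed in edgeR, over all genes or adjusted over the list alone, or in DESeq2, with 6 at an unadjusted p under 0.05. Jon65Aiv, a digestive protease gene, measured 82.0 ± 67.6 and 9.63 ± 7.96 CPM. Trypsin and Jonah genes summed to 35.2 CPM in Dam replicate 1, within the 25.4 to 90.6 CPM of the Dam Pol II libraries, and to 546 and 585 CPM in Dam replicates 2 and 3, so that these 2 libraries carried the difference in those genes. Ribosome biogenesis genes were negative in 19 of 20 with a median of -0.27 (camera adjusted p = 2.47e-05; adjusted p = 0.858 with an estimated correlation). Of these 1 passed adjusted over the list alone, Non1 at 645 ± 56.8 and 350 ± 14.7 CPM. Camera also called detoxification genes (median 0.17), mitochondrial ribosomal proteins (0.15) and complex I (0.15) higher, and piRNA pathway (-0.10) and photoreceptor genes (-0.44) lower. Their adjusted p was 0.00364, 0.000522, 0.0133, 0.0316 and 0.00747, and with an estimated correlation 0.858 for each.

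In all, 7 genes were called higher and 1 lower of 9630 tested in whole females, and the arms did not overlap for 18.8% of genes, against 10% by chance. None of the 8 stayed called whichever library was left out. All 8 kept their direction, which leaving out 1 library can hardly change for a called gene. The edgeR count was 0 without Dam replicate 2 or without Dam Pol II replicate 2 (793 and 872 at an unadjusted p under 0.05), 2 without Dam Pol II replicate 3, 4 without Dam Pol II replicate 1 and 19 without Dam replicate 3. DESeq2 called 276 genes. In the simulated counts for whole females 15 of 88 edgeR calls were false. With the replicate number as a block 2 genes were called, 1 of them among the 8, though the numbers were not shown to pair libraries.

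In ovary many genes changed by small amounts with Dam Pol II. Eggshell genes parted in direction: Vm26Ab rose from 1558 ± 96.6 to 2530 ± 460 CPM (log2 fold change 0.70, SE 0.12, adjusted p = 0.0250) and Vml by 0.43 (SE 0.08, adjusted p = 0.0362), both encoding vitelline membrane proteins. Of the 19 vitelline membrane and chorion genes 2 were called higher, 0 lower and 17 not, and adjusted over the list alone 5 were higher (Vm26Ab, Vml, Vm26Aa, psd and Vm34Ca, of 0.43 to 0.70) and 4 lower (Cp7Fc -0.43, Cp18 -0.90, Fcp3C -0.38 and Cp16 -0.70). The list as a whole was not called by camera (adjusted p = 0.825). Yp3 rose by 0.55 (SE 0.08, adjusted p = 0.0201) and all 3 yolk protein genes were higher adjusted over the list alone (median 0.47; camera adjusted p = 2.98e-05; adjusted p = 0.456 with an estimated correlation).

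Ribosome biogenesis genes lay lower in ovary, with 19 of 20 negative and a median of -0.17, which was 0.31 when scaled to the ERCC counts, against 0.52 for all genes. Polr1A, the largest subunit of RNA polymerase I, fell from 164 ± 8.68 to 129 ± 5.74 CPM (-0.34, SE 0.06, adjusted p = 0.0250), and 9 members were lower adjusted over the list alone (camera adjusted p = 1.53e-07; adjusted p = 0.456 with an estimated correlation). Cytosolic ribosomal protein genes were negative in 80 of 85, with a median of -0.10 (0.43 when scaled to the ERCC counts), and none passed over all genes tested in edgeR or adjusted over the list alone, with 22 at an unadjusted p under 0.05 and 8 called by DESeq2 (camera adjusted p = 5.15e-08; adjusted p = 0.814 with an estimated correlation). Among heat shock genes 2 rose and 2 fell of 13 measured, and adjusted over the list alone 2 rose and 3 fell. The small heat shock gene Hsp27 rose by 0.34 (SE 0.06, adjusted p = 0.0412). The stress-linked lncRNA:Hsromega fell from 294 ± 38.2 to 157 ± 16.9 CPM (-0.91, SE 0.10, adjusted p = 0.00852) and the chaperone cofactor gene stv fell as well (-1.01, SE 0.18, adjusted p = 0.0294). The list was not called by camera (adjusted p = 0.261). Camera also called detoxification genes (median 0.14), proteasome subunits (0.06) and fat body markers (0.43) higher and muscle markers lower (-0.43), with adjusted p of 0.00235, 0.0019, 0.00919 and 0.000143. With an estimated correlation these were 0.456, 0.745, 0.456 and 0.745.

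Among called genes with a mean of at least 5 CPM, the largest rises in ovary were in CG9380 (2.35, SE 0.43, adjusted p = 0.0329), lncRNA:CR43496 (1.58, SE 0.17, adjusted p = 0.00852), the photolyase gene phr6-4 (1.38, SE 0.18, adjusted p = 0.0125), Ugt301D1, a UDP-glycosyltransferase (1.00, SE 0.18, adjusted p = 0.0315) and CG9331 (0.94, SE 0.14, adjusted p = 0.0176). CG6961, Dhit and CG7675 rose by 0.52 to 0.70, and the list members GstE1 by 0.42 and squ, a piRNA pathway gene, by 0.48. Lsp2 rose from 0.5 ± 0.406 to 5.25 ± 2.47 CPM (3.37, SE 0.57, adjusted p = 0.0250). The largest falls among such genes were in FBgn0010549 (-4.40, SE 0.69, adjusted p = 0.0204), daw, an activin-like ligand (-3.54, SE 0.38, adjusted p = 0.00852), CG4839 (-1.88, SE 0.27, adjusted p = 0.0176), the clock gene vri (-1.14, SE 0.20, adjusted p = 0.0315) and udd (-1.08, SE 0.17, adjusted p = 0.0201), a factor for rRNA gene transcription. CG31999, CG31926 and Drip fell by between 0.92 and 1.00, and the muscle gene Prm by 0.51.

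Of 7541 genes tested in ovary 33 were called higher and 51 lower, 18 of them by at least 2-fold, and the arms did not overlap for 23.4% of genes, against 10% by chance. None of the 84 stayed called whichever library was left out. All 84 kept their direction, which leaving out 1 library can hardly change for a called gene. Ovary Dam Pol II replicates 2 and 3 also held transcripts, of a source not tested, that were lower in replicate 1, such as Mur18B at 22.8 and 67.0 CPM against 2.32 CPM. How far RNA of the same source added to the rises of other genes was not tested. Among the rises named above, Ugt301D1 and CG9331 had values of -1.43 and -0.88 in testis in the fit of all 24 libraries, while Lsp2 had 0.47. The number of called genes was 1 without Dam replicate 3, 3 without Dam replicate 2, 9 without Dam replicate 1, 16 without Dam Pol II replicate 2 and 530 without Dam Pol II replicate 3. It was 281 with Dam Pol II replicate 1 alone against the 3 Dam libraries, 70 of the 84 genes among them.

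In testis ribosomal protein genes lay lower with Dam Pol II, while ribosome biogenesis genes were positive in 14 of 20 (median 0.06, camera adjusted p = 0.64). Of 90 measured cytosolic ribosomal protein genes 89 were negative, with a median of -0.36, which was 0.46 when scaled to the ERCC counts, against 0.79 for all genes. RpL22 measured 24.8 ± 5.07 and 14.2 ± 2.21 CPM and RpL5 260 ± 40.2 and 181 ± 13.2 CPM. None of the 90 passed over all genes tested in edgeR, while 68 were lower adjusted over the list alone, 71 had an unadjusted p under 0.05 and DESeq2 called 12 (camera adjusted p = 4.49e-26; adjusted p = 0.707 with an estimated correlation). Mitochondrial ribosomal protein genes (median -0.13) and complex I genes (median -0.14), with medians of 0.60 and 0.61 when scaled to the ERCC counts, were also called lower by camera, with adjusted p of 0.0387 and 0.00296. Genes of the female germline list (median 0.19) and of the piRNA pathway (median 0.19) were called higher, with adjusted p of 0.0387 and 0.00971. With an estimated correlation the adjusted p of these 4 lists was 0.756, 0.745, 0.707 and 0.707.

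Single genes called in testis reached large fold changes. lncRNA:CR43263 had no count in any Dam library and 29.4 ± 4.89 CPM with Dam Pol II, at least 217-fold higher (adjusted p = 6.69e-05). CG33669 rose from 0.05 ± 0.0866 to 23.5 ± 5.32 CPM (log2 fold change 8.61, SE 0.49, adjusted p = 4.43e-05). Muc30E, lncRNA:CR44919, meso18E, Apoltp, ChLD3, lncRNA:CR44971 and CG32006 rose by 1.23 to 1.6. Among called genes with a mean of at least 5 CPM, the largest falls were in FBgn0030737 (-4.34, SE 0.79, adjusted p = 0.0455), the cytochrome P450 gene Cyp4p1 (-3.03, SE 0.50, adjusted p = 0.0308), the tetraspanin gene Tsp29Fb (-2.74, SE 0.32, adjusted p = 0.00627), Ugt49B1 (-2.70, SE 0.38, adjusted p = 0.0142) and lncRNA:CR44300 (-2.65, SE 0.33, adjusted p = 0.00656). The near-identical amylase genes Amy-p and Amy-d, which can share reads, fell from 82.4 ± 32.9 to 16.8 ± 1.99 CPM and from 65.5 ± 26.1 to 16.2 ± 3.76 CPM (adjusted p = 0.00656 and 0.0188), and MsrA, CG15096 and CG30026 fell by between 1.66 and 2.11. Detoxification genes were called lower as a list (median -0.19, or 0.60 when scaled to the ERCC counts; camera adjusted p = 0.00108; adjusted p = 0.707 with an estimated correlation). Its member Cyp6g1 moved with Dam replicates 2 and 3, at 36.6 and 36.9 CPM against 3.90 CPM in Dam replicate 1. With that library alone against Dam Pol II the list detoxification and oxidative stress genes, testis, was still called (median -0.158, camera adjusted p = 0.00559).

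Testis Dam replicates 2 and 3 held 29 transcripts at 10 CPM or more that lay under 2 CPM in the other 4 testis libraries. Mur18B, for example, measured 478 and 513 CPM there and 1.16 CPM in Dam replicate 1. How far RNA of the same source added to the falls of other genes was not tested. Among the falls named above, Tsp29Fb and Ugt49B1 had values of 1.46 and 1.10 in ovary in the fit of all 24 libraries, while FBgn0030737 had -0.18. Of 11011 genes tested 22 were called higher and 42 lower, 54 of them by at least 2-fold, and the arms did not overlap for 19.7% of genes, against 10% by chance. The genes that stayed called whichever library was left out were CG33669, lncRNA:CR43263, lncRNA:CR44070 and lncRNA:CR44612, 4 of the 64. All 64 kept their direction, which leaving out 1 library can hardly change for a called gene. With Dam replicate 1 alone against the 3 Dam Pol II libraries 234 genes were called, 38 of the 64 among them. The count was 4 without Dam Pol II replicate 2, 9 without Dam Pol II replicate 3, 17 without Dam Pol II replicate 1, 32 without Dam replicate 2, 185 without Dam replicate 1 and 1528 without Dam replicate 3. The number of called lists was 6, and 2 without Dam replicate 1 and 3 without Dam replicate 2.

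**Figure D2:**
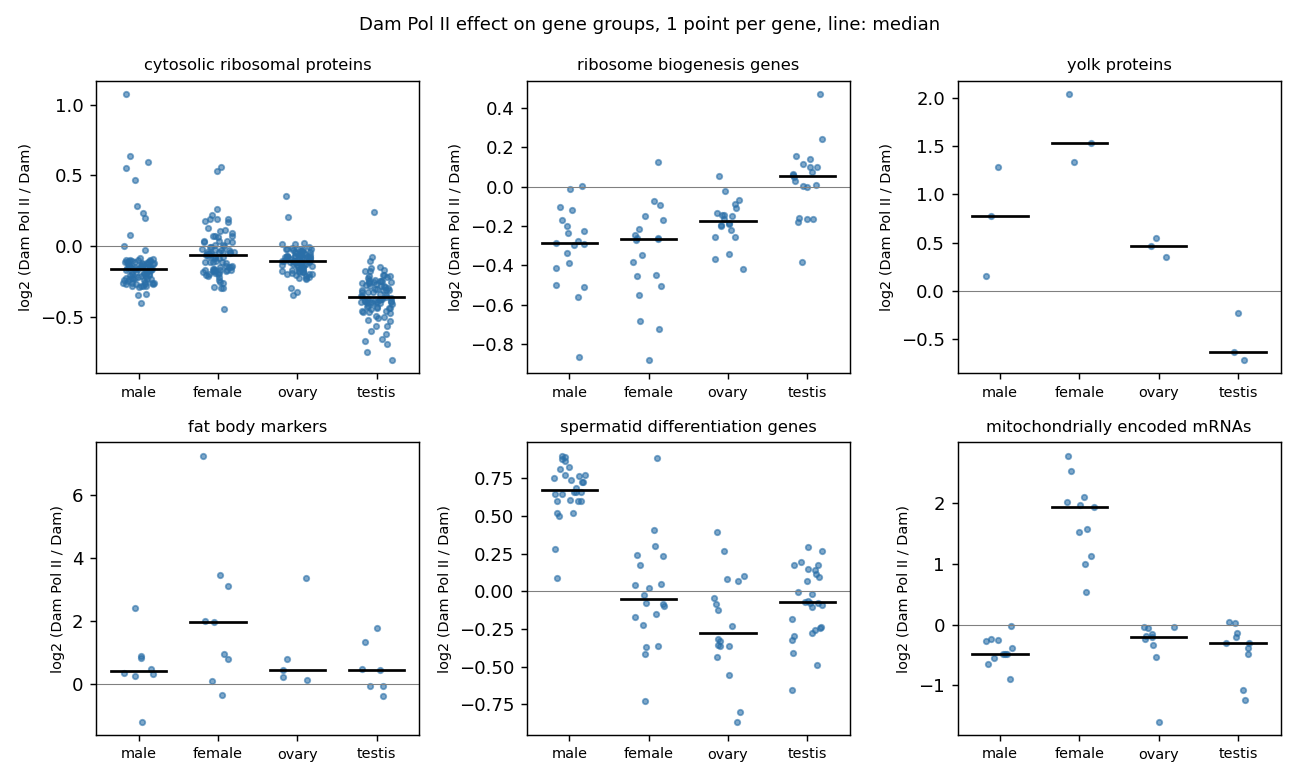
Log2 ratio of Dam Pol II to Dam for the measured genes of 6 groups in the 4 tissues, with 1 point per gene, a line at the median and a separate axis per group. Ribosomal protein genes had a median of -0.36 in testis (0.46 when scaled to the ERCC counts), and mitochondrially encoded mRNAs 1.93 in whole females.

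Calls were compared between tissues to see whether the same genes changed with the transgene. Polr2A, the gene whose coding sequence the transgene carries, was the only gene shared between whole males, whole females and testis, so that this overlap says nothing about other genes. Lsp2 was called higher in whole females and ovary (adjusted p = 0.0632, Fisher's exact test). Orai, a calcium channel gene chosen after its values were seen, was called in ovary and testis (0.34 and 0.73 on the log2 scale; adjusted p = 0.0628). Neither overlap passed. No gene was called in all 4 tissues. Of 83 genes called in ovary and measured in whole females 67 had the same sign there, 80.7% against 59.2% of all genes measured in both, and in whole males it was 55 of 76 (72.4% against 53.1%). In testis 30 of 77 genes called in ovary had the same sign (39.0% against 48.4%). Of genes called in testis the same sign was found for 28 of 45 in whole males (62.2% against 46.6%), 14 of 40 in whole females (35.0% against 41.6%) and 13 of 23 in ovary (56.5% against 48.4%).

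The effect of Dam Pol II differed between testis and ovary for 28 of 13258 genes in the fit of all 24 libraries, 3 with a larger and 25 with a smaller value in testis. Of the 28 genes 11 were among the 29 transcripts that testis Dam replicates 2 and 3 held, and 10 of these 11 were also higher in ovary Dam Pol II replicates 2 and 3 than in every other ovary library. With testis Dam replicate 1 and ovary Dam Pol II replicate 1 as the only libraries of their groups 2 genes were called, 1 of them among the 28. Galphas, a G protein subunit gene, measured 0.26 in ovary and -1.55 in testis (difference -1.81, SE 0.24, adjusted p = 0.00254). Between whole males and whole females 10 genes differed: Polr2A with a larger value in males, and Lsp2 and 8 mitochondrially encoded mRNAs with smaller ones, such as mt:ND5 at -0.27 and 1.96 (difference -2.24, SE 0.31, adjusted p = 0.00363). A fit of only the 12 libraries of whole animals called 1 gene, and leaving out mitochondrial genes 2, each among the 10. Of 50 assignments of the transgene drawn within tissues, the real one included, 12 called as many genes between whole males and whole females. Chance is thus not excluded for the count of 10. The draws weigh the number of genes called and not any single gene, such as Polr2A. Among the 4 tissues 57 genes differed, and 8 genes, 6 of them among the 57, with the same libraries of testis and ovary left out. Without testis Dam replicate 1 the testis against ovary count was 93, without ovary Dam Pol II replicate 1 it was 54, and without any 1 of the other libraries but testis Dam replicate 3 it was 9 to 14. Without whole male Dam replicate 1 the males against females count was 164. In the test of where the Dam Pol II effect differs among the 4 tissues the count was 554 without that library, 118 without testis Dam replicate 1 and 18 to 22 without testis Dam replicate 2 or any 1 of the testis Dam Pol II libraries.

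The sexes were compared in the Dam libraries, as a measure of the tissues themselves. Whole males exceeded whole females in reproductive tract transcripts: all 21 accessory gland and ejaculatory duct or bulb markers were called lower in females, with a median log2 fold change of -10.21. Ebp, an ejaculatory bulb protein gene, measured 13168 ± 6063 CPM in males and 3.96 ± 1.37 CPM in females (-11.71, SE 0.69). Of 26 spermatid differentiation genes 25 were called lower (median -6.33), and the dosage compensation RNA lncRNA:roX2 measured 30.8 ± 5.36 and 0.0902 ± 0.156 CPM (-7.94, SE 0.65). Whole females had higher levels of all 3 yolk protein genes (median 9.51), all 18 measured vitelline membrane and chorion genes (median 8.37), all 21 DNA replication and cell cycle genes (median 4.29), 20 of 21 piRNA pathway genes (median 3.47) and all 20 ribosome biogenesis genes (median 2.38). Counts adjusted over the list alone were the same for these 7 lists. Camera called each of them with an adjusted p of at most 0.000132, and with an estimated correlation the adjusted p lay between 0.307 and 0.433.

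Of 11317 genes tested between whole animals 2939 were called higher and 3324 lower in females. Genes at 0 in all male Dam libraries included CG42705, at least 444-fold higher in females, and Send1, at least 389-fold higher, a gene of the spermathecal glands. CG9997, a seminal fluid protein gene, was at 0 in all female Dam libraries and at least 1966-fold lower. Polr2A was higher in females by 1.25 (SE 0.17, adjusted p = 0.000684) in the Dam libraries.

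Ovary and testis differed in most genes, those of the germline and the eggshell among them. All 28 spermatid differentiation genes (median -10.59) and all 12 meiotic arrest genes (median -8.22, or -7.40 with genes at 0 set to their bound) were called lower in ovary. The spermatid gene janB measured 750 ± 47.6 CPM in testis and 0.472 ± 0.285 CPM in ovary, and the meiotic arrest gene can 49.2 ± 10.3 and 0.0686 ± 0.0595 CPM. Ovary was higher in all 19 vitelline membrane and chorion genes (median 9.03), 3 of 3 yolk protein genes (median 7.25), 18 of 22 female germline genes (median 3.56, 4 lower), 20 of 21 piRNA pathway genes (median 1.92), 20 of 21 DNA replication genes (median 3.26) and all 20 ribosome biogenesis genes (median 2.80). The germ plasm organiser osk measured 1.68 ± 0.247 CPM in testis and 978 ± 114 CPM in ovary. Of 90 cytosolic ribosomal protein genes 83 were higher in ovary (median 2.09) and 7 lower. The latter included RpS19b (-7.72, SE 0.26), RpL10Aa (-11.01, SE 0.39) and RpL22-like, which had no count in ovary and was at least 1151-fold lower. Of 39 complex I genes 3 were higher and 33 lower (median -1.18), the latter including ND-51L2 (-11.25, SE 0.33). Adjusted over the list alone the counts of these lists were the same, and camera called each with an adjusted p of at most 0.0180, which was 0.166 for the eggshell list and at least 0.668 for the others with an estimated correlation.

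**Figure D3:**
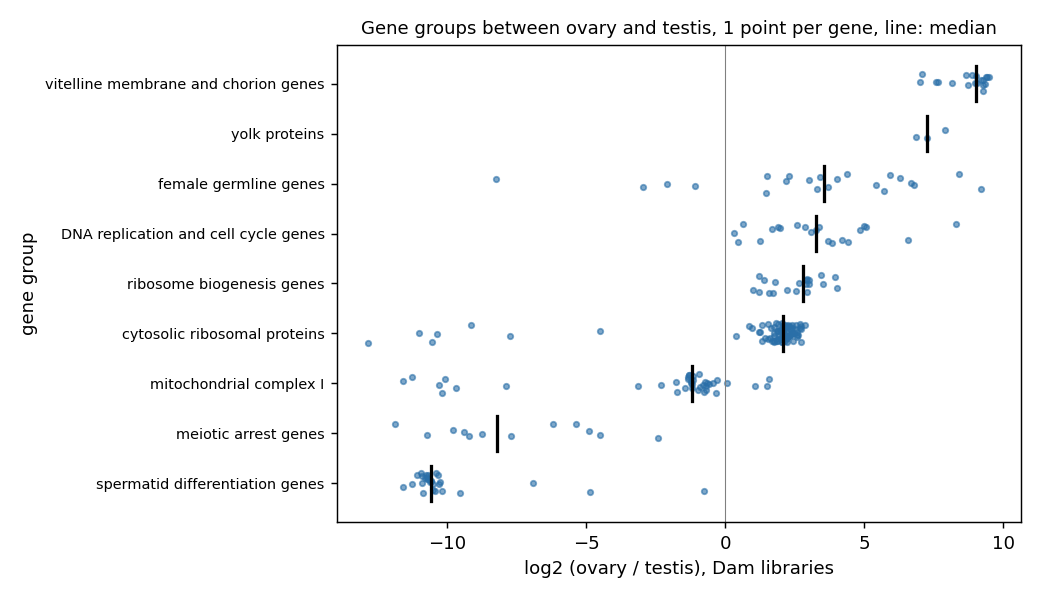
Log2 ratio of ovary to testis in the Dam libraries for the genes of 9 groups, with 1 point per gene and a line at the median; points of genes at 0 in one organ are fitted values. Medians run from -10.59 for spermatid differentiation genes to 9.03 for vitelline membrane and chorion genes.

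Of 10953 genes tested between gonads 4407 were called higher and 5480 lower in ovary. TMM scaling takes most genes as unchanged, while most were called here. Every testis library had a lower TMM factor than every ovary library. Replicate 2 with Dam, for example, had 0.758 in testis and 1.378 in ovary. The log2 fold changes, the list medians above and the numbers called higher and lower rest on this scaling. The mucin-related gene Mur11Da was at least 936-fold higher in ovary and CG15172 at least 2228-fold lower, with no count in testis and ovary respectively. Under TMM scaling Polr2A measured 2.89 higher in ovary (SE 0.18, adjusted p = 2.16e-11).

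Intergenic regions held a larger share of counts in testis than in ovary. The share was 0.474 ± 0.0227% of gene and intergenic counts in testis and 0.112 ± 0.00694% in ovary (SD, n = 6 each), a difference of 0.362 points (exact permutation p = 0.00216, the smallest possible; adjusted p = 0.0108). Between Dam Pol II and Dam no difference of any size could pass, as 0.1 is the smallest p that 3 against 3 can give. The exact permutation p was 0.2 in whole males (0.276% with Dam, 0.290% with Dam Pol II), 0.1 in whole females (0.137% and 0.112%), 0.6 in ovary (0.110% and 0.114%) and 0.3 in testis (0.485% and 0.463%). With mitochondrial genes and regions left out, the whole female shares were 0.174% and 0.169% (exact permutation p = 0.7). Whole males reached 0.276 to 0.290% against 0.112 to 0.137% in whole females as group means, a contrast that was not tested.

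Single intergenic regions changed with Dam Pol II in each tissue, counted without strand. In ovary the region on 2R from 5032896 to 5065136, next to the troponin gene TpnC41C, rose from 0.0461 ± 0.0799 to 5.14 ± 1.24 CPM (6.35, SE 0.68, adjusted p = 2.56e-09), and that on 2L from 8355273 to 8355577, next to Mur29B, rose by 1.19 (SE 0.32, adjusted p = 0.0132). The region Un_CP007101v1 from 1 to 24503 rose there from 7.51 ± 1.61 to 20.4 ± 5.48 CPM (1.45, SE 0.24, adjusted p = 3.99e-05). It was also called higher in whole females (2.11, SE 0.50, adjusted p = 0.0487). In testis the region on 2L from 15275192 to 15277696, next to UK114, had no count with Dam and 3.07 ± 1.23 CPM with Dam Pol II (adjusted p = 5.79e-06). The region on 2L from 10017564 to 10026575, next to CG13127, fell from 1.49 ± 0.158 to 0.147 ± 0.0709 CPM (-3.24, SE 0.57). That on 2R from 17145927 to 17154488, next to CG17290, fell from 1.94 ± 0.405 to 0.328 ± 0.0436 CPM (-2.55, SE 0.46). Lower levels of these testis regions, and of the ovary region next to TpnC41C, lay within or below the floors of 0.265 to 0.920 CPM. The sizes of these changes are therefore uncertain. Of the named regions only Un_CP007101v1 in ovary and the whole male region below reached the mean of 5 CPM asked by the rule. Other called regions also reached it. The ovary region on 3L next to CG6511 fell from 8.59 ± 1.78 to 4.64 ± 1.54 CPM (-0.90, SE 0.26). The testis region on 2L next to CG31693 fell from 46.8 ± 11.5 to 19.1 ± 5.99 CPM (-1.28, SE 0.20). That on X next to lncRNA:CR40469 rose in testis from 32.7 ± 3.73 to 48.5 ± 2.56 CPM (0.57, SE 0.15). In whole females the region on 2L from 14358865 to 14359151, next to Rab14, rose from 0.518 ± 0.433 to 5.10 ± 1.62 CPM (3.23, SE 0.56, adjusted p = 0.0141), and in whole males that on 2R from 16819341 to 16824563, next to CG34459, fell (-2.21, SE 0.48, adjusted p = 0.0427). Called regions numbered 1 lower of 251 tested in whole males, 6 higher and 2 lower of 107 in whole females, 3 higher and 4 lower of 95 in ovary and 8 higher and 15 lower of 754 in testis. In whole males 24 regions were called without Dam replicate 1, 0 without Dam replicate 3, 2 without Dam Pol II replicate 1 and 4 without Dam Pol II replicate 3. In whole females the count was 16 without Dam replicate 1 or 3, 3 without Dam replicate 2 or Dam Pol II replicate 1, 0 without Dam Pol II replicate 2 and 5 without Dam Pol II replicate 3. In ovary it was 2 without Dam replicate 2 and 3 without Dam Pol II replicate 1, and in testis 9 without Dam replicate 1, 61 without Dam replicate 3 and 6 without Dam Pol II replicate 2.

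**Figure D4:**
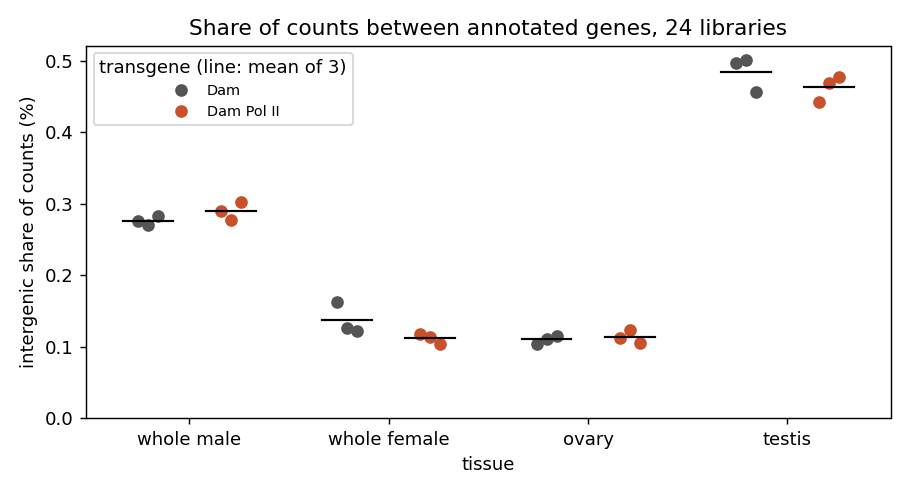
Share of gene and intergenic counts that fell in intergenic regions, in percent, in each of the 24 libraries by tissue and transgene; each point is a library and each line the mean of 3. The testis means of 0.485% and 0.463% lie above the ovary means of 0.110% and 0.114%.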

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

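The tests of midgut and of accessory gland or ejaculatory duct RNA, and the 3 tests of the mitochondrial mRNAs, were chosen only after the result was seen. The patterns in single replicates, in mitochondrial mRNAs and in ribosomal protein genes were themselves found in the data. The list of Malpighian tubule genes was not among the lists set before the data were examined.

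The effect of Dam Pol II differed between testis and ovary for 28 genes in the interaction test. The 5 with the smallest p were CG12769 (-3.43, adjusted p = 0.000373), Galphas (-1.81, adjusted p = 0.00254), Ndae1 (-3.38, adjusted p = 0.00264), Pvf2 (-4.35, adjusted p = 0.00612) and Mur18B (-12.96, adjusted p = 0.00612), as log2 differences of testis minus ovary. Of 50 assignments of the transgene drawn within tissues, the real one included, 1 called as many genes. The highest of the others called 22. Such a count was rare among the draws, but so few draws do not exclude chance. They also cannot tell the transgene from transcripts that set certain replicates of a group apart. The transgene is thus not shown to be the source of this count. Of the 28 genes 11, Mur18B included, were among the 29 transcripts that set testis Dam replicates 2 and 3 apart, and 10 of these were also higher in ovary Dam Pol II replicates 2 and 3 than in every other ovary library. With testis Dam replicate 1 as the only testis Dam library and ovary Dam Pol II replicate 1 as the only library of its group, 2 genes were called, 1 of them among the 28.

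Between whole males and whole females the effect differed for 10 genes, the 5 with the smallest p being mt:ND3 (-3.64, adjusted p = 0.00363), mt:ND5 (-2.24, adjusted p = 0.00363), mt:ND1 (-2.51, adjusted p = 0.00453), mt:CoI (-1.92, adjusted p = 0.0052) and Polr2A (2.76, adjusted p = 0.00536), as males minus females. Here 12 of the 50 drawn assignments called as many, and the highest other called 432, so that chance is not excluded. The reason for such high counts was not tested. The real count also rose when whole male Dam replicate 1 was left out, as given above. Among the 4 tissues the effect differed for 57 genes; 9 of the 50 drawn assignments called as many, with 740 as the highest other, so that chance is not excluded there either.

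Testis Dam replicates 2 and 3 held 29 transcripts at 10 CPM or more that lay under 2 CPM in the other 4 testis libraries, with summed levels of 1520 and 1472 CPM against 9.11 to 12.2 CPM and a median of 0.309 of the whole male Dam level. The tables argue against accessory gland or ejaculatory duct RNA, since 0 of 20 measured genes of those organs were higher in both libraries than in every other testis library. They also argue against midgut RNA as a source common to both libraries. Trypsin and Jonah genes together reached 0.000926 and 0.0153 of their whole male level in the 2 libraries. These genes summed to 22.0 CPM in Dam replicate 3, against 1.21 to 2.03 CPM in the other testis libraries. Some midgut RNA in Dam replicate 3 is therefore not excluded. Of the other gut genes on the list Amy-p and Amy-d were tested in testis, and they did not follow the pattern, with Amy-p at 102 CPM in Dam replicate 1 and 101 and 44.5 CPM in replicates 2 and 3. RNA from Malpighian tubules stays open as a candidate source, as 5 of 7 measured genes of a list of 9 were higher in both libraries. Of these, Irk3 and salt were also among the 29 transcripts, so that their higher levels were fixed by how those were chosen. The others were Uro, Irk1 and ClC-a. No biological explanation was tested, since the design gives none for a difference between replicates.

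In whole females 10 of 11 mitochondrially encoded mRNAs were higher in every Dam Pol II library than in every Dam library, with a median log2 fold change of 1.93, against -0.47 in whole males. All mitochondrial RNA took 30.6 to 39.11% of gene counts with Dam Pol II and 15.49 to 28.25% with Dam. The large mitochondrial rRNA rose by 0.90 (SE 0.39, adjusted p = 0.438), within the range of the mRNAs (0.53 to 2.78). Its log2 fold change was lower than the median of the mRNAs by 1.03 (difference -1.03). A higher share of all mitochondrial RNA was thus present, but the rRNA did not match the median rise of the mRNAs. Muscle markers had a median of 0.04 (0.0439), which argues against a higher share of muscle RNA. Read depth of the libraries stays open, since 2 of the 3 Dam Pol II libraries were deeper than every Dam library and the third was not. Other tissue markers moved in the same comparison, with a median of 1.97 for fat body and -2.25 for gut markers, though trypsin and Jonah genes lay at the Dam Pol II level in Dam replicate 1 (35.2 CPM in sum), so that a changed mix of tissues stays open. An effect of the transgene and a difference in age, mating or collection of the females were not tested and stay open too. Plate position and genetic background, which went with the transgene, were not tested either and stay open.

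In testis 89 of 90 cytosolic ribosomal protein genes were lower with Dam Pol II, with a median of -0.36 (0.46 when scaled to the ERCC counts, against 0.79 for all genes). Genes matched on length and level, 607 in number, had a median of -0.107, which argues against gene length bias as the whole cause. Testis Dam replicate 1, which lacked the 29 transcripts above, exceeded the Dam Pol II mean by 0.281 in its median log2 level of these genes, which argues against RNA of another organ in Dam replicates 2 and 3 as the cause. Muscle markers had a median of -0.59 (11 of 14 negative) and hemocyte markers 0.63 (4 of 5 positive) in the same comparison. An effect of the transgene or a different mix of testis cell types may account for the pattern. So may plate position or genetic background, and none of these was tested.

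The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 split, the real one, called as many. The real counts were 1, 8, 84 and 64 genes in whole males, whole females, ovary and testis and 6263 and 9887 between the sexes and the gonads, and the highest of the other splits was 0 in each. For intergenic regions the real counts were 1, 8, 7 and 23, and the highest other was 0, 0, 0 and 1.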

How the results depend on the processing

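The alternatives that left out mitochondrial genes, or libraries with transcripts near 0 in other replicates of their group, were chosen after seeing the data. Over the alternatives run, single genes kept their direction and their side of the threshold in 3636 values, were no longer called in 409, became called in 81 and reversed in 24, over 314 results. Gene lists did so in 263, 90, 0 and 2 over 38 results, and intergenic regions in 232, 119, 0 and 0 over 39. Where no construction of the alternative shows it, the cause was not tested. The spread between replicates limits small changes of single genes most in whole animals, where the common biological coefficient of variation was 0.312 in males and 0.252 in females, against 0.0647 in ovary and 0.138 in testis.

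In whole males, against 1 called gene, the DESeq2 Wald test called 20, a fit of all 24 libraries 13, the pool 78A libraries 1210 and the same scaled by ERCC counts 4521. In whole females, against 8, the Wald test called 276, no filter 64, the replicate block 2 (the replicate numbers were not shown to pair libraries), all 24 libraries 95, pool 78A 0 with 1 Dam Pol II library assumed to vary like the Dam libraries, and leaving out mitochondrial genes 4. In ovary, against 84, the Wald test called 154, no filter 395, the block 135, a minimum absolute log2 fold change of 1 18, all 24 libraries 4, pool 78A 9, ERCC scaling 6073 and Dam Pol II replicate 1 alone against 3 Dam 281. In testis, against 64, the Wald test called 272, no filter 190, the block 162, the filter of 5 CPM 29, all 24 libraries 141, pool 78A 9, ERCC scaling 6597 and Dam replicate 1 alone against 3 Dam Pol II 234. The lone library of an arm was assumed to vary like the other groups.

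With an estimated correlation 0 lists were called in each tissue, against 12, 13, 7 and 6. Regions in whole males numbered 7 with their own TMM factors, 6 with no filter and 11 with the block, against 1; in whole females 1 with their own factors, against 8; in ovary 4 with no filter, against 7. The testis against ovary interaction called 93 genes in a fit of the 12 libraries of both tissues and 2 without the libraries with transcripts near 0 in other replicates of their group, against 28. The males against females interaction called 1 in its 12 libraries and 2 without mitochondrial genes, against 10. That among the 4 tissues called 8 without the libraries with transcripts near 0 in other replicates of their group, against 57. Shared calls numbered 8 in the fit of all 24 libraries, against 3. The intergenic share of testis minus ovary was 0.323 points without the 10 regions with most counts and 0.338 with regions of at least 1000 bp. With both ERCC pools the ERCC share of Dam Pol II minus Dam was 0.0396 points in whole males, 0.0242 in whole females, -0.00373 in ovary and -0.0138 in testis.

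With each library left out in turn the called genes numbered 0 to 1 in whole males, 0 to 19 in whole females, 1 to 530 in ovary and 4 to 1528 in testis. Lists numbered 8 to 15, 10 to 14, 6 to 10 and 2 to 9, and regions 0 to 24, 0 to 16, 2 to 8 and 6 to 61. The testis against ovary interaction gave 9 to 93 and the males against females one 7 to 164. Where the Dam Pol II effect differs among the 4 tissues, 18 to 554 genes were called. The sex comparison gave 5344 to 6455 genes between whole animals and 9970 to 10171 between gonads.

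ERCC scaling raised all genes together in whole males, ovary and testis, so that small negative values had to turn and the reversals show no dependence of single genes. Under it values reversed in whole males for Myc (0.43), ND-AGGG (0.057), lncRNA:roX2 (0.39), msl-3 (0.91), wupA (0.31), up (0.37), Amy-d (0.49), epsilonTry (0.29), VGlut (0.61), Rdl (0.80), Rh4 (0.69) and Rh6 (0.73). In ovary they did for RpL36 (0.26), RpL41 (0.20), Polr1A (0.13) and the result for LanB1, ovary (0.0262). In testis they did for RpL22 (0.15), RpL5 (0.35), mRpS21 (0.18), mRpL36 (0.32), ND-B14.5A (0.0666) and the result for ND-B8, testis (0.0862). With Dam Pol II in place of Dam libraries the female minus male values of Polr2A (-1.49) and PGRP-SC2 (0.16) reversed; for Polr2A reads of the transgene can then count toward the gene. For list detoxification and oxidative stress genes, whole male, the test reversed without Dam replicate 1, and with each library left out the median ran from 0.0442 to 0.383. For list cytosolic ribosomal proteins, whole male, the test reversed without Dam replicate 3, and the median ran from -0.376 to -0.00127.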

Other observations

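In ovary 5 genes encoding basement membrane proteins, chosen after their values were seen and because they were called, fell with Dam Pol II. The type IV collagen genes vkg and Col4a1 fell from 103 ± 7.67 to 57.9 ± 8.60 CPM (SD, n = 3; log2 fold change -0.83, SE 0.10, adjusted p = 0.00852) and from 129 ± 17.4 to 77.8 ± 16.3 CPM (-0.73, adjusted p = 0.0362). The laminin genes LanA and LanB1 fell by 0.62 and 0.42 (adjusted p = 0.0243 and 0.0378) and the perlecan gene trol by 0.59 (adjusted p = 0.0388). No list of basement membrane genes was tested, so the values hold for these genes alone. Markers of other cell types were lower in the same comparison, with a median of -0.43 for muscle (12 of 14 negative) and -0.25 for hemocyte markers (3 of 3 negative), and a changed mix of cell types was not tested. When scaled to the ERCC counts the log2 fold change of LanB1, ovary, was 0.0262, against 0.52 for the median of all genes.

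Orai, which encodes a store-operated calcium channel and was also chosen after its values were seen, rose in testis from 39.1 ± 1.93 to 65.1 ± 2.26 CPM (0.73, SE 0.10, adjusted p = 0.0127) and in ovary by 0.34 (adjusted p = 0.0490). The log2 fold changes of all genes correlated with r = 0.295 between whole males and whole females, 0.312 between whole females and ovary and 0.135 between whole males and ovary. With testis r was -0.0174 for whole males, -0.0869 for whole females and -0.0636 for ovary. These values run across genes, which are not independent replicates.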
